A study of Homo sapiens with 6 samples.

How the data were processed

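MM.1S, a human multiple myeloma cell line, had been transduced by lentivirus with a short hairpin RNA (shRNA) against the histone demethylase gene KDM6B or, as the control, against luciferase, and selected with puromycin, per the labels' protocols. Each arm had 3 libraries, called here shLuc replicates 1 to 3 and shKDM6B replicates 1 to 3. Total RNA was converted to libraries with a kit that, as far as its name in the labels shows, does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The labels speak of transduction in triplicate and do not say that cultures were kept apart afterwards; p-values measure the spread between these libraries, which may be technical.

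The authors deposited 1 table of raw counts per library and a table of normalized values of the whole series. Per the submitters' processing notes, STAR, featureCounts and DESeq were used with GRCh37 (hg19); versions, the annotation, strand setting, treatment of multi-mapping reads and any removal of duplicate reads are not given in the sources used here. The count tables list gene symbols without coordinates, so none are given. The deposited counts are whole numbers for 56637 symbols per library, and 1 line per library whose name had turned into a date was left out. The deposited normalized values, a signal on a linear scale, equalled each library's counts divided by 1 factor per library, to within 1e-06. That table holds 28 names turned into dates, and 56609 of its genes were matched to the counts. Totals were 7338393, 8844319 and 8996159 counts in shLuc replicates 1 to 3, and 7952156, 8485739 and 9848351 in shKDM6B replicates 1 to 3.

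The raw counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group, TMM scaling, and the quasi-likelihood test (glmQLFit, glmQLFTest) with the group as the single term, all 6 libraries together. P-values were adjusted by Benjamini-Hochberg over the 13839 genes tested, and a gene counted as past the threshold at an adjusted p under 0.05. Higher and lower always mean shKDM6B relative to shLuc. The standard error (SE) of a log2 fold change is the one implied by the quasi-likelihood statistic. Expression is given as TMM-scaled CPM with the SD over 3 libraries. Each p named as adjusted below comes from this test unless another tool is named.

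In a test on simulated data with the means, library sizes and dispersions of these libraries, 13670 genes were tested. The fit called 64% of 50 genes changed by 1.2-fold and 79.6% of 49 changed by 1.5-fold. It called 93.6% of 47 changed by 2-fold and 100% of 50 changed by 3-fold. All other genes were left unchanged, whereas 5405 genes passed in the real data. Counts that vary less than independent counting, as those of some dense genes did, were not simulated. These shares are therefore not the power of the real test. Of 181 simulated calls, 16 were unchanged genes.

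Before the data were examined, 28 gene lists were fixed, 19 on the biology of the line and the target and 9 on quality or other cell types. Lists with at least 5 tested members, 22 in all, were compared with the remaining genes by camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 22. Camera was repeated with an estimated correlation, and fry was run as an alternative. Counts of members "adjusted over the list alone" come from the same p-values adjusted within a list. Older symbols in the files were matched through a synonym table (CXCL8 is listed as IL8, JCHAIN as IGJ and TIGAR as C12orf5).

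The genes named were chosen by a rule fixed in advance. It took KDM6B, KDM6A, EZH2, ELK1, FOS, MYC and IRF4 by name. It then took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, and for each biology list up to 4 members past the threshold with the smallest p. Other genes are named as chosen after their values were seen.

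Alternatives fixed in advance were DESeq2 size factors and upper-quartile scaling in edgeR, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library in turn, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2 of the authors' normalized values plus 1, an adjusted p threshold of 0.01, camera with an estimated correlation and fry. After the data had been seen, 2 were added: leaving out the 3 libraries with keratin counts, and TMM scaling taken from 3341 genes with under 0.03 counts per base of exon.

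Pairs of libraries were compared by a chi-square of counts over genes with under 0.03 counts per base and at least 20 counts in the pair. Within a group, the chi-square per degree of freedom ran from 1.07 to 1.23, and the largest p of the 6 pairs was 0.0019. Every replicate pair thus differed slightly beyond counting noise, and each library was counted as 1 sample. That spread may be technical and does not show that the libraries came from separate cultures. The common dispersion of the main fit corresponds to a coefficient of variation of 3.23% between replicates. Exon lengths and 3′ UTR sequences came from a GENCODE release on GRCh38 and were used by gene name only: 35456 of the 56637 symbols were matched, 1097 of them through a synonym, and 90.7% of tested genes had a length. Counts per base are the mean count over 6 libraries divided by the length of a gene's exons. Intervals for sums of counts are exact Poisson 95% intervals and cover counting error alone. Word screens and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.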

Results

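RNA was sequenced from MM.1S cells, a line derived from a human plasma cell cancer, after lentiviral transduction with an shRNA against KDM6B or against luciferase. KDM6B (also known as JMJD3) is a demethylase that removes methyl groups from lysine 27 of histone H3. The files hold 3 shLuc and 3 shKDM6B libraries, with 7338393 to 8996159 counts per shLuc library and 7952156 to 9848351 per shKDM6B library. The comparison asks which genes differ in expression between the shKDM6B and shLuc libraries. No second KDM6B hairpin or rescue is named among the groups. Effects of KDM6B depletion therefore cannot be told apart from other effects of the hairpin sequences.

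KDM6B, the target, was lower in every shKDM6B library. Its raw counts were 409, 505 and 437 in shLuc replicates 1 to 3 and 239, 270 and 348 in shKDM6B replicates 1 to 3. The level went from 53.8 ± 4.9 CPM (SD, n = 3) to 32.6 ± 2.4 CPM (SD, n = 3), 61.1% of the control (log2 fold change -0.71, SE 0.073, adjusted p = 7.72e-08).

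The immediate-early transcription factors FOS and FOSB and the interferon-induced genes IFIT3 and TRIM22 were among the genes that fell most. The adenylate kinase AK4, the arginine synthesis enzyme ASS1, the scaffold protein AHNAK and the amino acid transporters SLC7A2 and SLC6A9 were among those that rose most. In all, 5405 of 13839 tested genes (39.1%) passed the threshold, 2783 higher and 2622 lower. Many of these changes were small: 2105 of the 5405 (38.9%) were under 1.2-fold, and 439 reached 2-fold, 147 higher and 292 lower (697 with no filter on low counts). The 3 shKDM6B values lay wholly above or below the 3 shLuc values for 48.4% of tested genes, where chance gives 10%. Correlations of log2 CPM were 0.994 to 0.995 within groups and 0.981 to 0.983 between them, and the first principal component held 64.3% of the variance. With scaling taken from genes with few counts per base, an alternative added after the data were seen, 3219 genes were higher and 1772 lower, 64.5% higher against 51.5%; with upper-quartile scaling, fixed in advance, 2514 were higher and 2913 lower, 46.3% higher. The scaling from genes with few counts per base ended the calls of KDM6A, EED, HYOU1, ERN1, DDB2, BCL2 and CD9, with adjusted p values from 0.114 to 0.635.

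Among the 10 largest falls, LSAMP, a neural cell adhesion molecule, fell by 3.88 on the log2 scale, and FOSB fell from 42.6 ± 17.5 to 3.37 ± 1.10 CPM (SD, n = 3 each). TRIM22 (-3.36), IFIT3 (-3.07) and FOS (-2.88) followed. The complement receptor C3AR1 (-2.41), the sphingolipid synthesis gene SPTLC3 (-2.38), the selenoprotein SEPP1 (-2.17) and SGK223 (-2.08) were also among them. Among the 10 largest rises, AK4 went from 10.9 ± 0.8 to 61.9 ± 3.1 CPM (SD, n = 3 each; log2 fold change 2.51, SE 0.080, adjusted p = 1.48e-15). AHNAK rose from 44.4 ± 2.4 to 220.2 ± 23.8 CPM (SD, n = 3 each). ASS1 (2.33), SLC7A2 (2.04), SLC6A9 (1.82), the ion channel ASIC1 (1.78), CYB561 (1.73), the glutathione-degrading enzyme CHAC1 (1.73), the innate immune kinase IRAK2 (1.72) and OSTM1 (1.64) made up the rest. AK4 and ASS1 have pseudogene copies, so part of their reads may have been split or lost in counting.

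**Figure D1:**
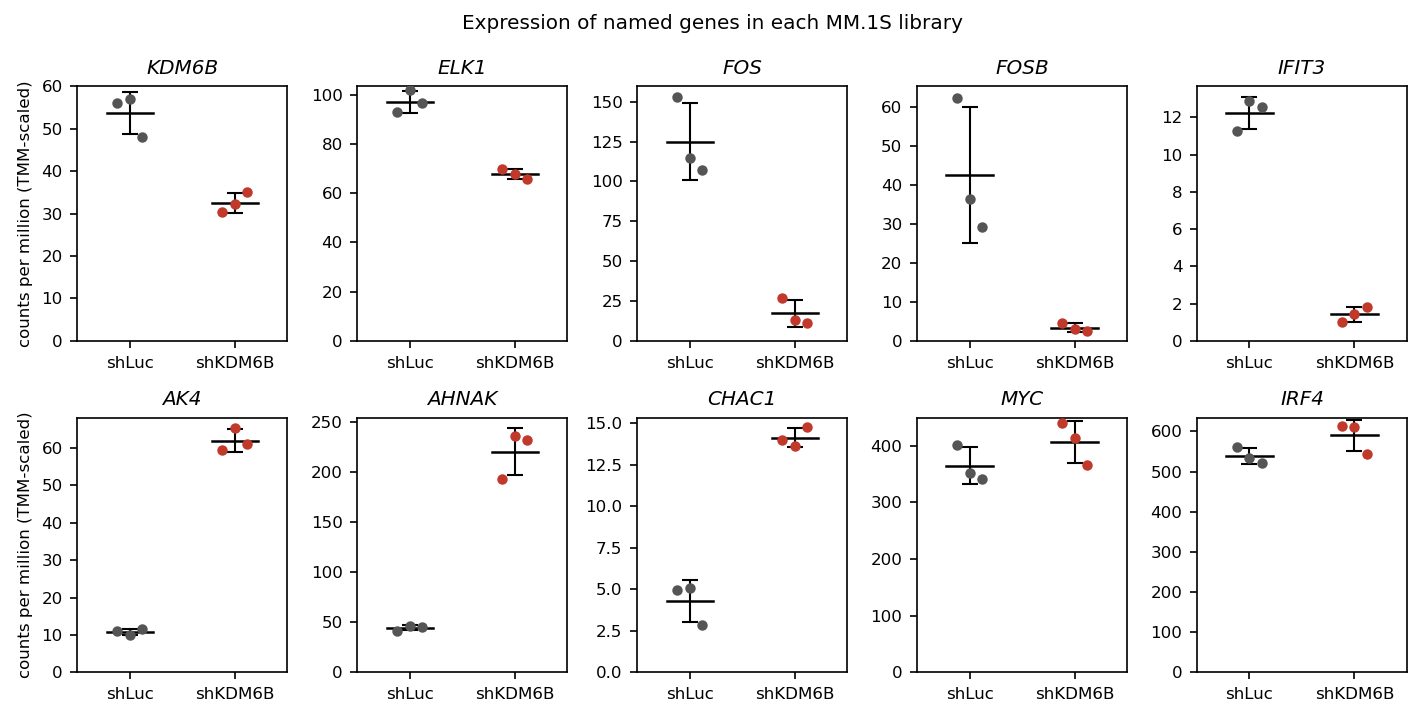
TMM-scaled CPM (y axis, linear and starting at 0) of 10 genes in the 3 shLuc and 3 shKDM6B libraries; points are libraries, black lines the group mean and bars the SD over 3 libraries. KDM6B falls from a mean of 53.8 to 32.6 and FOS from 125 to 17.3, while MYC and IRF4 overlap between groups.

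Genes induced by the ERK kinase pathway moved strongly, more of them down than up. Of 20 tested members, 7 were higher, 11 lower and 2 did not pass; adjusted over the list alone, the counts were again 7 higher and 11 lower. FOS fell from 125 ± 24 to 17.3 ± 8.5 CPM (SD, n = 3 each; log2 fold change -2.88, SE 0.16, adjusted p = 8.49e-12). PHLDA1 (-1.17) and the pathway inhibitor SPRED2 (-0.84) were also lower, and the ERK phosphatase DUSP5 was higher (0.72). As a list it was lower than the other genes by camera (adjusted p = 8.89e-05; adjusted p = 0.941 with an estimated correlation). Chosen after their values were seen, EGR1 (-3.51, SE 0.27), EGR2 (-2.84, SE 0.46) and JUN (-0.67, SE 0.075) were lower. CCND1, the cyclin D1 gene, was higher (1.27, SE 0.36, adjusted p = 0.00713). EGR2 and CCND1 had 0.0040 and 0.0028 counts per base, so the sizes of their changes rest on few counts.

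Components of the RAS-RAF-MEK-ERK cascade itself went both ways, with 5 of 25 higher, 9 lower and 11 not past the threshold; adjusted over the list alone, 5 were higher and 9 lower. ELK1, a transcription factor phosphorylated by ERK, fell from 97.1 ± 4.4 to 67.8 ± 2.1 CPM (SD, n = 3 each; log2 fold change -0.52, SE 0.049, adjusted p = 1.85e-08). The exchange factor RASGRP3 (-0.67) and HRAS (-0.60) were lower, and the kinases RPS6KA2 (0.97) and MKNK1 (0.79) were higher. The list did not pass by camera (adjusted p = 0.700); its median (-0.024) and the test pointed down and its mean (0.033) up.

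Genes of the type I interferon response were mostly lower. Of 16 tested members, 2 were higher, 12 lower and 2 not past the threshold, with the same counts of 2 and 12 adjusted over the list alone. IFIT3 fell from 12.2 ± 0.9 to 1.42 ± 0.40 CPM (SD, n = 3 each; log2 fold change -3.07, SE 0.20, adjusted p = 6.06e-11). IFIT1 (-1.88), OAS1 (-0.69) and IFIT5 (-0.47) were lower as well. By camera the list was lower than the other genes (adjusted p = 0.00455; adjusted p = 0.941 with an estimated correlation).

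Genes of the ATF4 amino acid response were mostly higher: 11 of 20 rose, 3 fell and 6 did not pass, and adjusted over the list alone 12 were higher and 3 lower. CHAC1 rose from 4.30 ± 1.24 to 14.1 ± 0.6 CPM (SD, n = 3 each; log2 fold change 1.73, SE 0.16, adjusted p = 1.74e-08). The cystine transporter SLC7A11 (0.96), CEBPB (0.69) and the serine synthesis enzyme PSAT1 (0.64) were higher. ATF4 itself, a gene chosen after its value was seen, had a log2 fold change of -0.057 (SE 0.052, adjusted p = 0.414). The list was higher by camera (adjusted p = 0.00967; adjusted p = 0.941 with an estimated correlation).

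**Figure D2:**
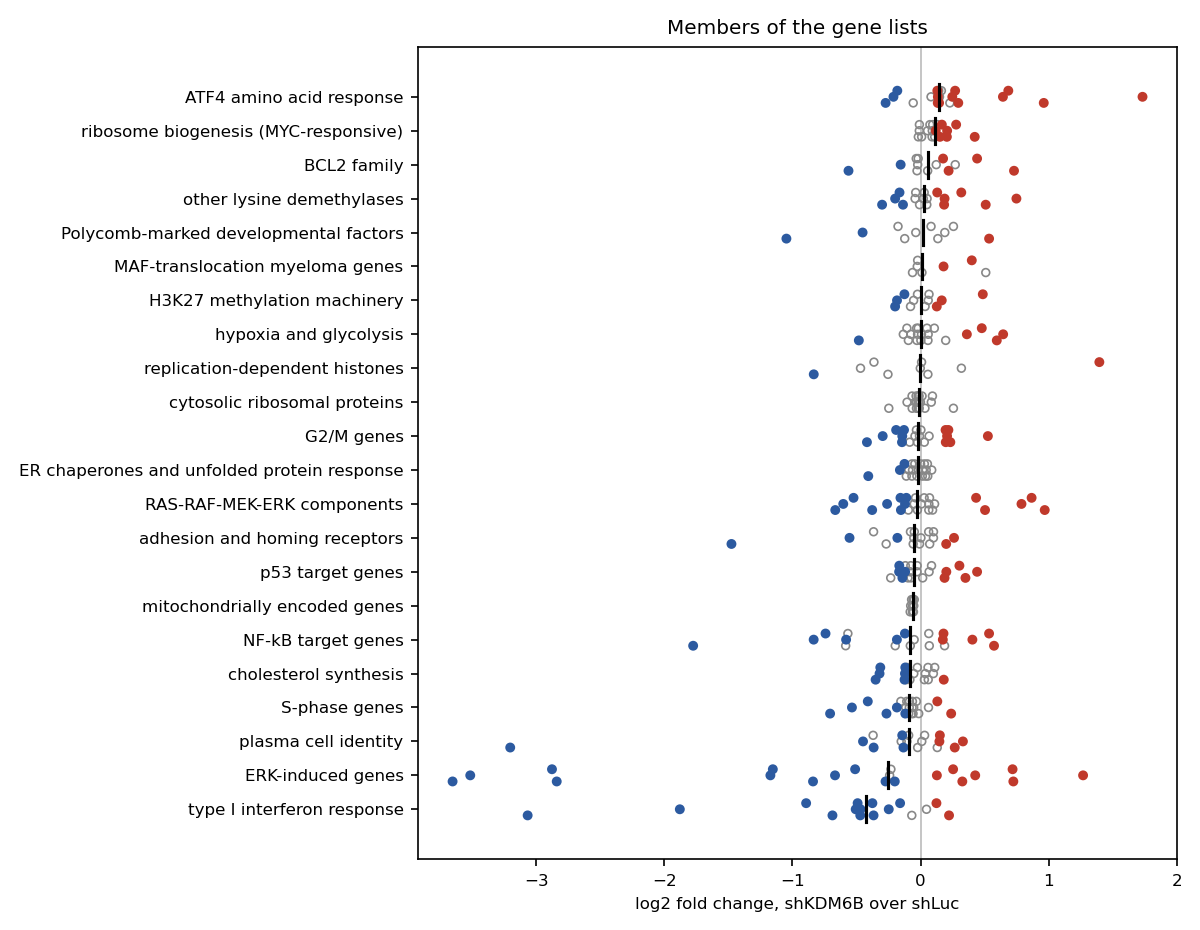
Log2 fold change of shKDM6B over shLuc (x axis) of every tested member of the 22 lists with at least 5 tested members, ordered by the list's median (black bar). Filled points passed the threshold, red higher and blue lower; open points did not. The type I interferon list has a median of -0.42, the ERK-induced list -0.26 and the ATF4 list 0.15.

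In the list of H3K27 methylation genes, 3 of 12 members were higher, 3 lower and 6 not past the threshold, and the counts adjusted over the list alone were 3 and 3. SUZ12, a Polycomb subunit that also has a pseudogene copy, was higher (0.49), as was AEBP2 (0.17), and EED was lower (-0.20). KDM6A, the other H3K27 demethylase in the list, was lower by a small amount (log2 fold change -0.18, SE 0.059, adjusted p = 0.0164). The DESeq2 Wald test gave the KDM6A change an adjusted p of 0.0831, and without shKDM6B replicate 1, shKDM6B replicate 3 or shLuc replicate 3 it was 0.0926, 0.0534 and 0.0607. AEBP2 lost its call without shLuc replicate 1, shLuc replicate 2 or shKDM6B replicate 3 (adjusted p = 0.0890, 0.0894 and 0.128), and by DESeq2 both AEBP2 (0.145) and EED (0.0715) missed the threshold. The methyltransferase EZH2 stood at 136 ± 4 and 139.3 ± 2.4 CPM (SD, n = 3 each; log2 fold change 0.036, SE 0.042, adjusted p = 0.543). The list of other lysine demethylases, which also holds the related gene JMJD6, went both ways. Of its 17 members 6 were higher, 4 lower and 7 not past the threshold, and again 6 and 4 adjusted over the list alone. KDM1B (0.75), KDM7A (0.51) and JMJD6 (0.32) were higher and JMJD1C was lower (-0.30). Neither list passed by camera (adjusted p = 0.740 and 0.700).

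Developmental factors that Polycomb commonly marks were mostly at low counts, and 10 of the 30 were tested. Of these 1 was higher, PAX6 (0.54), 2 were lower, SOX11 (-0.45) among them, and 7 did not pass, with the same counts adjusted over the list alone. PAX6 lost its call without shLuc replicate 1 (adjusted p = 0.108) and without shKDM6B replicate 3 (adjusted p = 0.147), and by DESeq2 (adjusted p = 0.104). The list did not pass by camera (adjusted p = 0.740); its median was 0.023, its mean -0.064 and the test pointed down.

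Plasma cell genes were split, with 4 of 17 higher, 5 lower and 8 not past the threshold, or 5 higher and 7 lower adjusted over the list alone. FCRL5, a surface receptor of plasma cells, fell by 3.20 on the log2 scale, from raw counts of 48, 59 and 47 to 7, 7 and 3. CD38 (-0.45) and TNFRSF17, the gene of the surface protein BCMA (-0.37), were lower and FKBP11 was higher (0.33). IRF4 had a log2 fold change of 0.13 (SE 0.053, adjusted p = 0.0550) and MYC of 0.16 (SE 0.063, adjusted p = 0.0551), both just short of the threshold. Without shLuc replicate 1 both passed (adjusted p = 0.0236 and 0.00278), as they did without shKDM6B replicate 3 (adjusted p = 0.00468 and 0.00303). These are the shallowest shLuc and the deepest shKDM6B library. Within each group the CPM of IRF4 and of MYC fell as library totals rose. The passes may therefore follow from the shifted balance of depth and are no firmer evidence of a rise. The plasma cell list did not pass by camera (adjusted p = 0.659).

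Of 19 tested NF-kB target genes, 5 were higher, 6 lower and 8 not past the threshold, or 5 higher and 8 lower adjusted over the list alone. BIRC3 (0.57) and NFKB1 (0.40) were higher, and the chemokine CCL5 (-0.83) and TRAF1 (-0.58) were lower. Genes of MAF-translocated myeloma, the subtype of this line, were higher in 2 of 7, NUAK1 (0.40) and CCR1 (0.18). The other 5 were not past the threshold, and the same 2 passed adjusted over the list alone. Of the 5, ITGB7 (1.745 counts per base), CCND2 (0.98), DEPTOR (0.94) and MAF (0.74) are dense in reads. Counts of such genes grew less than the depth, as described below. A change in them could therefore be missed, and the lack of calls does not show stable expression. Among 17 adhesion and homing receptors 2 were higher, 3 lower and 12 not past the threshold, as when adjusted over the list alone. CCR10 (-0.55) and CD9 (-0.18) were lower and CXCR4 was higher (0.20). By DESeq2 the adjusted p of CD9 was 0.0670. Camera gave adjusted p values of 0.740, 0.659 and 0.659 for these 3 lists.

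S-phase genes were lower in 6 of 22 and higher in 2, with 14 not past the threshold and the same counts adjusted over the list alone. The replication factors GINS1 (-0.71) and GINS2 (-0.41), cyclin E2 (CCNE2, -0.54) and POLA1 (-0.27) were lower. By camera the S-phase list had an adjusted p of 0.0793, and it passed, with the same direction, without shKDM6B replicate 1 (adjusted p = 0.0329) and without shKDM6B replicate 2 (adjusted p = 0.0474); with all libraries and an estimated correlation it did not (adjusted p = 0.941). As for MYC and IRF4, leaving out a library shifts the balance of depth between groups, which may bear on these passes. G2/M genes were higher in 6 of 20 and lower in 6, with 8 not past the threshold and 6 and 6 adjusted over the list alone. The mitotic motor KIF11 (0.53) and NUSAP1 (0.22) were higher and CENPE (-0.42) and CENPF (-0.30) lower. The G2/M list had an adjusted p of 0.961 by camera, with a median of -0.017, a mean of 0.0081 and the test pointing up, or down under some alternatives.

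Ribosome biogenesis genes were higher in 7 of 19 and lower in 0, with 12 not past the threshold; adjusted over the list alone 6 were higher and 0 lower. RRP9 (0.42), RRP12 (0.28), POLR1B (0.21) and WDR43 (0.17) were higher. The list had an adjusted p of 0.0749 by camera and passed without shLuc replicate 1 (adjusted p = 0.00782) and without shKDM6B replicate 3 (adjusted p = 0.00513); with all libraries and an estimated correlation it did not (adjusted p = 0.941). Here too the passes came with a shifted balance of depth between groups. Cholesterol synthesis genes were lower in 6 of 19 and higher in 1, with 12 not past the threshold and the same counts adjusted over the list alone. HMGCS1 (-0.32), INSIG1 (-0.31) and STARD4 (-0.35) were lower and DHCR7 was higher (0.18). Of 20 hypoxia and glycolysis genes 4 were higher, 1 lower and 15 not past the threshold, as when adjusted over the list alone. The glucose transporter SLC2A1 (0.65), PFKFB3 (0.60) and NDRG1 (0.48) were higher and hexokinase HK2 was lower (-0.48). ER chaperone and unfolded protein response genes were lower in 3 of 20, higher in 0 and not past the threshold in 17, and 2 were lower adjusted over the list alone. The 3 were DNAJC3 (-0.41), HYOU1 (-0.16) and ERN1 (-0.13). ERN1 lost its call without shLuc replicate 2, shLuc replicate 3, shKDM6B replicate 1 or shKDM6B replicate 3, with adjusted p values from 0.0907 to 0.156. Camera gave adjusted p values of 0.659, 0.658 and 0.659 for the cholesterol, hypoxia and ER lists.

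Of 20 p53 target genes 5 were higher, 4 lower and 11 not past the threshold, or 5 and 5 adjusted over the list alone. BBC3, the gene of the pro-apoptotic protein PUMA (0.44), PLK3 (0.35) and FAS (0.19) were higher and DDB2 was lower (-0.17). The list had an adjusted p of 0.961 by camera, with a median of -0.051, a mean of 0.016 and the test pointing up, or down under some alternatives. Among 13 tested BCL2 family genes 4 were higher, 2 lower and 7 not past the threshold, as when adjusted over the list alone. BBC3 and BID (0.18) were higher, and PMAIP1 (-0.56) and BCL2 (-0.16) lower. That list had an adjusted p of 0.738 by camera.

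Keratin transcripts appeared in some libraries of both groups. KRT5 had raw counts of 28, 4 and 0 in shLuc replicates 1 to 3 and 53, 110 and 0 in shKDM6B replicates 1 to 3. Of the 3 tested epithelial markers, KRT5 and KRT19 were past the threshold as higher and EPCAM was not past it; adjusted over the list alone, EPCAM also passed as lower. Summed over 8 keratins and S100A2, CPM was 12.1, 1.81 and 1.45 in shLuc replicates 1 to 3 and 36.1, 48.3 and 0.812 in shKDM6B replicates 1 to 3. With shLuc replicate 1 and shKDM6B replicates 1 and 2 left out, 3859 genes passed, 2043 higher and 1816 lower, with the lone shKDM6B library assumed to vary like the others. In both fits 3590 genes passed, and 0 of them changed direction. Named genes that did not pass without these libraries were KDM6A, EED, CCNE2, FAS, DDB2, BCL2, WDR43, DHCR7, CD9, SOX11 and PAX6, with adjusted p values from 0.0506 to 0.154.

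**Figure D3:**
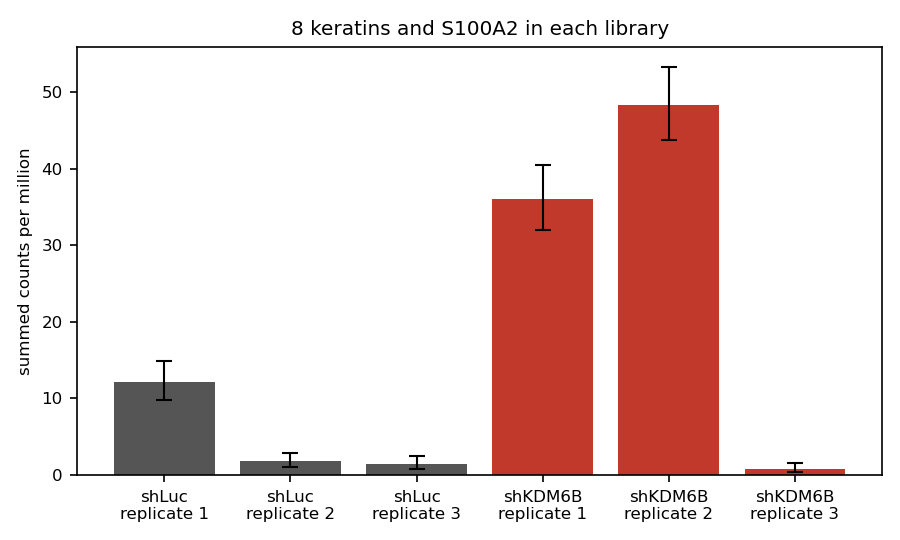
Summed CPM (y axis, starting at 0) of 8 keratins and S100A2 in each library, grey for shLuc and red for shKDM6B; bars on top are exact Poisson 95% intervals, counting error alone. shKDM6B replicates 1 and 2 stand at 36.1 and 48.3 and shKDM6B replicate 3 at 0.812.

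Markers of other cell types were few. Of 2 tested T cell markers CD3E was lower and 1 was not past the threshold, or 1 higher and 1 lower adjusted over the list alone. The tested monocyte marker, CD14, did not pass, and 0 fibroblast markers had enough counts to be tested. The erythroid gene HBB was lower (-0.81), over all genes and adjusted over the list alone. Of 2 tested mature B cell markers BACH2 was lower (-0.58) and CR2 was not past the threshold, as when adjusted over the list alone. Cytosolic ribosomal protein genes passed in 0 of 22 and mitochondrially encoded genes in 0 of 9 by the edgeR test. The mitochondrial counts hardly varied between any libraries, so a change in these genes could hardly have passed. Of 9 histone genes, HIST1H3D was higher (1.40), HIST1H2AC lower (-0.83) and 7 not past the threshold, as when adjusted over the list alone. Camera gave adjusted p values of 0.893, 0.738 and 0.740 for these 3 lists.

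Counts of genes dense in reads grew less with library size than those of other genes. MT-CO1, a mitochondrial gene, had between 1422 and 1430 counts in all 6 libraries, although library totals differed by up to 34.2%. Genes above 1 count per base of exon had 6.47% more counts in shKDM6B replicate 3 than in replicate 1, and genes up to 0.01 had 37.4% more. MYC (1.09 counts per base), IRF4 (0.816) and DUSP5 (0.846) lay in the dense range, and KDM6B (0.051) and AK4 (0.042) did not. The median size of the log2 fold change was 0.40 for genes up to 0.01 counts per base and 0.060 for those above 1. Sparse genes tend to hold few counts, so counting noise alone enlarges their fold changes, and the medians do not measure compression of dense genes. The share of genes past the threshold was 31.3% up to 0.01 counts per base, 46.9% from 0.03 to 0.1 and 8.11% above 1.

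**Figure D4:**
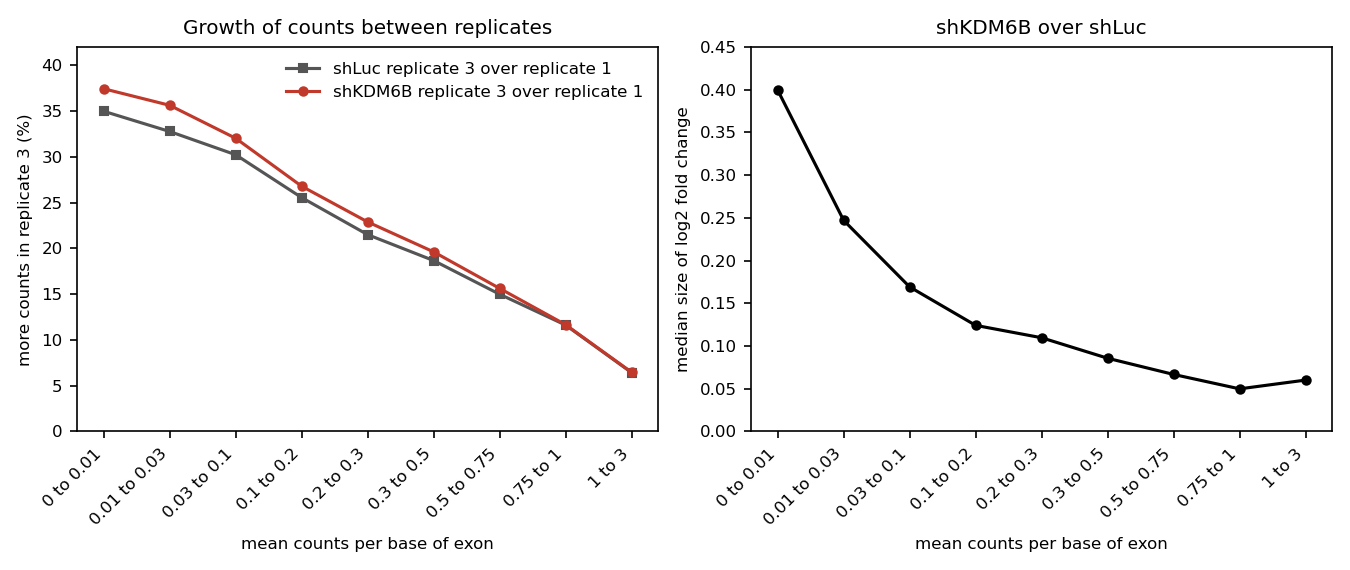
Left, percent more counts in replicate 3 than in replicate 1 of each group (y axis) by mean counts per base of exon (x axis, bins); right, median size of the log2 fold change of shKDM6B over shLuc in the same bins. In the shLuc pair the growth goes from 35.0% to 6.42% over the bins, and in the shKDM6B pair from 37.4% to 6.47%.

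Some 7-base words in 3′ UTRs went with the direction of change across genes. These words were picked by z from all screened genes, the named ones included, so the counts below are no separate test. At least 1 of the 4 words with the most negative z was in 21 of 47 lower named genes. Among them were RASGRP3, HRAS, CD38, TRIM22, IFIT1 and FCRL5. It was also in 12 of 42 higher named genes, such as AK4, ASIC1 and DUSP5. Over all screened genes at least 1 was in 47.0% of lower genes, 32.2% of higher and 30.5% of those not past the threshold. The named genes therefore do not stand out for these 4 words. At least 1 of the 3 words with the highest z was in 0 of the 47 and in 12 of the 42. Among the 12 were AK4, CYB561, MKNK1 and OSTM1. Over all screened genes it was in 11.0% of lower genes and 10.7% of those not past the threshold. It was in 21.5% of higher genes and 33.85% of those higher by at least 1.5-fold. FOS, FOSB, ELK1, PHLDA1 and IFIT3 have none of either, and the target KDM6B has none as well, so a lack of them does not clear a gene of hairpin effects.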

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

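Tests added after the data were seen are those without the 3 libraries with keratin counts and those scaled from genes with few counts per base. No result past the threshold reversed under the 19 alternatives, and 76 of the 92 named genes other than KDM6B kept their side of the threshold in each that tested them. The count of genes past the threshold, 5405, ran from 3821 (DESeq2 Wald test) to 6218 (replicate block), and 0 of the shared calls changed sign. The majority turned to lower genes with upper-quartile scaling (2514 higher, 2913 lower) and without shLuc replicate 1 (2486 higher, 2536 lower). With upper-quartile scaling the G2/M and p53 lists, which never passed, turned from up to down. KDM6B was lower throughout, with log2 fold changes from -0.79 to -0.58. The count of at least 2-fold changes, 439, was 697 with no filter on low counts, which tests 29100 genes, and 469 to 538 with 1 library left out.

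By fry, which does not set a list against the other genes, the ERK-induced, type I interferon and ATF4 lists had an adjusted p of 0.0187 each. The S-phase (0.114) and ribosome biogenesis (0.126) lists did not pass by fry. In camera with an estimated correlation the ERK-induced, type I interferon and ATF4 lists lost their calls, with an adjusted p of 0.941 each. The S-phase and ribosome biogenesis lists had the same, a value that most of the 22 lists shared. The values that follow are from camera with the preset correlation. The S-phase list passed with no filter (adjusted p = 0.00755), with the replicate block (0.0416) and without the 3 keratin libraries (0.00199), and ran from 0.0329 to 0.377 with 1 library left out. The ribosome biogenesis list passed with no filter (0.00211) and with the replicate block (0.0253), and ran from 0.00513 to 0.205 with 1 library left out. The ER chaperone list passed without the keratin libraries (0.0477). The cause was not tested. Leaving out libraries also shifts the balance of depth between groups, and counts of dense genes grew less than depth. These lists hold dense genes, such as PCNA (0.98 counts per base), NOLC1 (0.90) and CALR (0.94), beside sparser ones. Passes gained by leaving out libraries therefore cannot be told apart from an effect of depth. Genes that lost calls in at least 3 settings were KDM6A, ERN1, AEBP2, PAX6, EED and CD9, and IRF4 and MYC gained calls in 5 and 4.

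The shared replicate numbers were not taken as pairs: same-numbered libraries had correlated deviations from their group means of 0.12, -0.077 and 0.15, and 4 of the 6 libraries correlated best with their own number. The replicate block gave 6218 genes, and under it MYC (adjusted p = 0.000194) and IRF4 (0.00129) passed. On simulated data with the sizes and dispersions of these libraries, 64% of 50 genes changed by 1.2-fold were called. Far fewer genes were changed there than were called in the real data, so this is not the power of the real test. How far depth alone limits the calls was not tested.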

Other observations

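Genes of MHC class II antigen presentation, a group chosen after its values were seen, were mostly lower in the shKDM6B libraries. Of 10 tested members 8 were lower, 0 higher and 2 not past the threshold by edgeR's quasi-likelihood test. HLA-DRA fell from raw counts of 802, 877 and 885 in shLuc replicates 1 to 3 to 445, 461 and 534 in shKDM6B replicates 1 to 3 (log2 fold change -0.89, SE 0.054, adjusted p = 2.71e-11). HLA-DMB (-1.70), HLA-DPB1 (-1.35), HLA-DPA1 (-1.24) and HLA-DMA (-1.16) were lower, as were HLA-DRB1 (-1.38) and HLA-DRB5 (-1.58), whose near-identical sequences make their separate counts uncertain. The transactivator gene CIITA had a smaller fall (-0.23, adjusted p = 0.0114), and the invariant chain gene CD74 had a log2 fold change of -0.071 (SE 0.060, adjusted p = 0.372) at 0.72 counts per base. Of 10 MHC class I genes 2 were higher, 1 lower and 7 not past the threshold.

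The interferon-inducible guanylate-binding proteins, also chosen after their values were seen, were lower in 4 of 4 tested genes. The estimates were -2.90 (SE 0.39) for GBP4, -2.22 (SE 0.35) for GBP6, -1.59 for GBP1 and -0.21 for GBP3. The 2 largest rest on few reads. Raw counts of GBP4 were 17, 21 and 22 in shLuc replicates 1 to 3 and 1, 4 and 3 in shKDM6B replicates 1 to 3. Those of GBP6 were 15, 30 and 24 against 3, 5 and 7. Among 9 target genes of the oxysterol receptor LXR, chosen likewise, 5 were higher, 1 lower and 3 not past the threshold. The cholesterol exporters ABCG1 (1.46, adjusted p = 3.28e-06) and ABCA1 (1.16, adjusted p = 8.67e-11) rose most, and SCD was lower (-0.12).

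In the tests that follow, those of read density, of the knockdown as the source of keratins, of the word pair within KDM6B and of other splits of the libraries were chosen after the results were seen; the permutations, the words of the same letters and the 24 further epithelial markers were fixed before theirs. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5405 genes and 439 with at least a 2-fold change, 1 split each reaching that count. The highest of the other splits gave 0 for both. Each of those splits mixes shLuc and shKDM6B libraries in both arms, so the group difference becomes spread within arms. Their 0 calls were thus close to fixed in advance and do not measure false calls.

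Short words in 3′ UTRs went with lower genes. Over 10456 genes, with UTR length, base content and expression regressed out, GCACTCA (z = -7.33, 956 genes) and TGGAGGT (z = -7.06, 1729 genes) had the most negative shifts of 7-base words, against a largest size of 5.27 in 200 permutations of all words, and no other word of the letters of GCACTCA exceeded 0.455 of its shift once words that overlap it, such as AGCACTC (z = -6.96), were left out, which argues against chance and, for GCACTCA alone, against base content. A candidate explanation is that strands of the KDM6B hairpin repress other transcripts through seed matches: the words' cores, GCACTC as its reverse complement and GGAGGT, lie within 17 bases of the KDM6B coding sequence (GAGTGCGATGTGGAGGT, bases 5118 to 5134 of transcript KDM6B-201), as they do within 21 bases in 0.66% of the genes searched. RASGRP3, HRAS and CD38 have at least 1 of the 4 leading words, which were picked on these same genes, and FOS, FOSB, ELK1 and IFIT3 have none. Only the 3′ UTR of each gene's longest coding transcript was searched, and that of KDM6B, the target, has none of them. A lack of the words therefore does not clear a gene of direct or indirect hairpin effects. The hairpin sequences were not used here and no biological explanation was tested. The words GATTTGC (z = 9.75) and AATCGTC (z = 9.04) went with higher genes, AK4 has both, and they were not traced to a source. The control libraries carry a hairpin too, against luciferase, and genes it represses would read as higher in shKDM6B. That was not tested, so rises such as that of AK4 cannot be credited to KDM6B loss alone.

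Counts of genes dense in reads grew less than the depth, alike in both groups. Between replicates 3 and 1, genes above 1 count per base grew by 19.7% of the growth of the sparsest genes (log2 scale) in shKDM6B and by 20.7% in shLuc, so a difference in library size alone, which would give near 100%, is excluded. The 9 mitochondrial genes had a median variance over mean of 0.078 across the 6 libraries, far below that of independent counting. Removal of duplicate reads before counting may account for this, and the growth fell in every bin as that would require; whether it was done is not given in the sources used here. If so, fold changes of dense genes such as MYC, IRF4, CD74 and DUSP5 could be understated, and no biological explanation was tested.

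Epithelial transcripts stood out in shKDM6B replicates 1 and 2 and, less so, in shLuc replicate 1. In shKDM6B replicate 3 the summed CPM of 8 keratins and S100A2 was 6.70% of that in shLuc replicate 1, so the knockdown did not raise them in every library. These are the transcripts in which the pattern was first seen, and the low value is from a single shKDM6B library, so this is no separate test. RNA or reads of epithelial cells may be the source: of 24 further markers written down beforehand, 14 of the 18 with at least 6 counts had their highest CPM in shKDM6B replicate 1 or 2. Of the 14, KRT16 peaked in shKDM6B replicate 1 and the others in replicate 2, so this count says little about replicate 1. Of the 24, 4 had at least 20 counts in every library and so are transcribed in MM.1S or present throughout. PERP and ITGB4, which are among the 14, belong to these 4 and weaken the count further. The knockdown was first set against the summed 24 markers (206 CPM in shKDM6B replicate 3, 240 in shLuc replicate 1), and the sum was changed to the 9 transcripts once that was seen, since a few genes transcribed in MM.1S made up most of it. Carry-over of cells or RNA was not set against reads misassigned between libraries.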
